A study of Mus musculus with 26 samples.

How the data were processed

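RNA of CD4+ SMARTA T cells was measured by RNA-seq. Per the labels, the mice were of strain C57BL/6 and aged 6 to 16 weeks, total RNA was extracted with TRIzol and libraries were made with a PrepX kit. RNA selection, strandedness and sorting gates are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The labels name 26 libraries in 9 groups: naive spleen (2), day 7 splenic Th1 (4) and Tfh (4), day 7 IEL (3) and LPL (3), day 21 splenic Th1 (2) and Tfh (3), and day 21 IEL (3) and LPL (2). Each library was placed in its group by its description label, which also gave the replicate number. Per the submitters' processing notes, Bowtie2, STAR, featureCounts and DESeq2 were among the tools and mm10 was the genome build; versions and the role of each tool are not given in the sources used here.

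The values are TPM per gene, as deposited by the authors in a table of all libraries. TPM divides the reads of a gene by its length and scales each library to the same total, so a value depends on every other gene of the library, and a transcript that takes a large share lowers all others. The 26 columns summed to between 994199 and 998805. The table held 10721 genes, each above 5 TPM in at least 2 libraries. Mitochondrially encoded genes were not among them and were not analysed here, and 12 gene names had been turned into dates and were kept in the tests but not named. Low values of a gene were whole multiples of a common step, from which whole reads were recovered for 10710 genes (99.9%) with a relative tolerance of 1e-06. They summed to between 1731567 and 4455106 reads per library. In a test on 10710 simulated genes the recovery step returned reads for 99.96% of them, each exact in every library. These genes were simulated from the genes with recovered reads, so the test does not cover the 11 genes where recovery had failed. The recovered reads served to describe depth and for an added alternative. No interval for counting error is given, since the tests rest on the spread between libraries.

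Differences were tested on log2(TPM + 1), with a pseudocount of 1, with limma 3.58.1 in R 4.3.3. One linear model with a mean per group was fitted to all 26 libraries, so that the groups shared an estimate of the spread, and contrasts were moderated by empirical Bayes with an abundance trend and robust settings. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The 12 comparisons began with day 7 spleen against naive. At each day, Th1 was set against Tfh, intestine against Th1 and against Tfh, and IEL against LPL. Day 21 was set against day 7 in the intestine and in the spleen, and the interaction of time and tissue was tested. Intestine stands for the mean of the IEL and LPL groups, and spleen for that of the Th1 and Tfh groups. The design had been written for several possible units, and its branch for normalized values was used because the values are TPM.

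Of 28 gene lists, 22 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The 264 list p-values were adjusted by Benjamini-Hochberg within each comparison. Lists, comparisons and the rule for named genes were fixed before the data were examined. The rule took, for each list, up to 4 members with the largest absolute log2 fold change among those past the threshold, or 2 members as values where fewer than 2 passed. It also took the 3 highest and 3 lowest genes of a comparison among those that passed, averaged at least 5 TPM and had groups that did not overlap. The number was 6 of each in day 7 Th1 against Tfh, intestine against Th1 at either day, day 7 IEL against LPL and intestine day 21 against day 7. The overlap condition was not applied to the interaction. Predicted genes, receptor segments, sex-linked genes and members of the lists of other cell types were left out of that part, and so were Rn45s and the date-like names, an exclusion added after the table was seen. A further 13 fixed genes were given wherever measured. Some genes that the rule took are not reported here.

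Sequence sharing was measured on the GENCODE M21 annotation of GRCm38, the assembly called mm10 by the submitters. A gene's share is the percentage of its 50-base exon sequences that also occur in another annotated gene. Of the listed genes, 10297 (96.0%) had a share, 5369 shared none, 8770 shared under 5% and 262 shared at least 50%. Coordinates are from the same annotation, in which 349 of 351 named genes were found by symbol. Figures and joins were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

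The tests were run on simulated reads for 10710 genes with 200 changed genes, in 5 runs per comparison. Every gene was given the same dispersion (spread beyond sampling noise), 0.0241, a median over genes of the recovered reads. Changed genes were drawn only from those above a minimum of reads. Genes that vary more or have fewer reads would be missed more often, so the rates below hold for this setting only. A change of 2-fold was recovered for 91.2% of genes in the design of day 7 Th1 against Tfh and for 66.4% in that of day 21 Th1 against Tfh, and 3.24% and 3.71% of calls were false. In the design of day 7 spleen against naive, with 2 naive libraries, 82.4% were recovered and 8.40% of calls were false, above the nominal rate. In the design of day 7 IEL against LPL 84.8% of 2-fold changes were recovered, with 6.09% of calls false.

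Replicates of a group were compared before averaging and differed by more than sampling noise. The alternatives tried were unweighted TMM factors, cyclic loess, pseudocounts of 0.5 and 8, fits of only the groups compared, library weights, the replicate number as a block, and each library left out in turn. Added after seeing the data were TPM rescaled without Rn45s, limma-voom on the recovered reads, genes of at least 10 TPM in at least 2 libraries, genes sharing under 5% of their 50-base sequences, Tfh libraries only for the spleen, and fits without the 4 day 21 intestinal libraries with macrophage genes. A result counts as reversed under an alternative where its sign changes and it passes in at least one of the fits.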

Results

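RNA was sequenced from mouse CD4+ T cells of the SMARTA line, whose transgenic T cell receptor recognises a peptide of lymphocytic choriomeningitis virus (LCMV). The 26 libraries fall into 9 groups. Naive cells came from the spleen (2 libraries). After 7 days of LCMV infection, cells were taken from the spleen as Th1 (4 libraries) and T follicular helper (Tfh, 4 libraries) subsets and from the small intestine as intraepithelial (IEL, 3 libraries) and lamina propria (LPL, 3 libraries) lymphocytes. After 21 days the same subsets were represented by 2 Th1, 3 Tfh, 3 IEL and 2 LPL libraries. Th1 cells are the interferon-gamma producing effector helpers, Tfh cells the helpers of B cells. The labels do not give the markers by which the subsets were sorted, and they do not say whether libraries of a group came from separate mice. The p-values below therefore measure the spread between these libraries, which may be technical. A gene used to sort a subset would differ between subsets by construction.

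The reads recovered from the steps of the deposited TPM values summed to between 1731567 and 4455106 per library, over 10710 of the 10721 listed genes. The 11 genes without recovered reads are left out of these sums, which are therefore lower bounds for the listed genes. The ribosomal RNA locus Rn45s took from 6.33% to 34.7% of the TPM of a library. Folds are on the log2(TPM + 1) scale, which understates changes of low genes. Values after a log2 fold change are its standard error (SE) from limma.

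**Figure D1:**
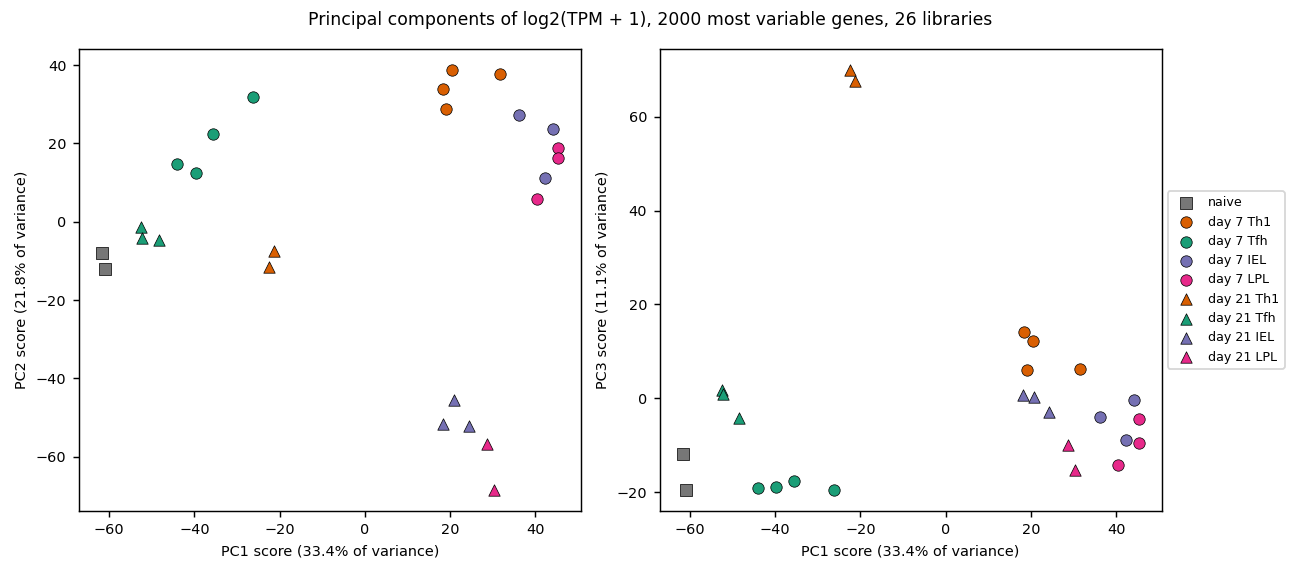
Principal component scores of the 26 libraries from log2(TPM + 1) of the 2000 most variable genes, with PC1 against PC2 on the left and PC1 against PC3 on the right. Squares are naive, circles day 7 and triangles day 21 libraries, and colors mark the subsets. PC1 holds 33.4%, PC2 21.8% and PC3 11.1% of the variance, and the 2 day 21 Th1 libraries stand alone on PC3 at 67.6 and 69.9.

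Cd4, the coreceptor that defines the lineage, had group means from 489.9 ± 174 TPM in day 7 IEL (SD, n = 3) to 906 ± 40.8 TPM in day 21 LPL (SD, n = 2). Cd3e, a chain of the receptor complex, was at 1251 ± 117 TPM (SD, n = 2) in day 21 Th1 libraries, while no other library exceeded 575 TPM. Tbx21, which encodes the Th1 transcription factor T-bet (chromosome 11, 97098071 to 97115331 of GRCm38, protein-coding), was at 3.77 ± 1.42 TPM (SD, n = 2) in naive cells and between 99.5 ± 21.9 TPM (day 7 Tfh, SD, n = 4) and 602 ± 166 TPM (day 21 IEL, SD, n = 3) in the infected groups. Cxcr5, the follicle-homing receptor (chromosome 9, 44511787 to 44561877), was at 615 ± 155 TPM (SD, n = 4) in day 7 Tfh cells and 259.6 ± 61.5 TPM (SD, n = 3) in day 21 Tfh cells, and at most 30.2 TPM in any library outside the Tfh groups. Cd69, whose product retains lymphocytes in tissue (chromosome 6, 129267325 to 129275436), was at 1860.2 ± 219 TPM (SD, n = 3) and 4427 ± 998 TPM (SD, n = 3) in day 7 and day 21 IEL, and at 782 ± 301 TPM (SD, n = 3) and 1861 ± 755 TPM (SD, n = 2) in LPL.

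**Figure D2:**
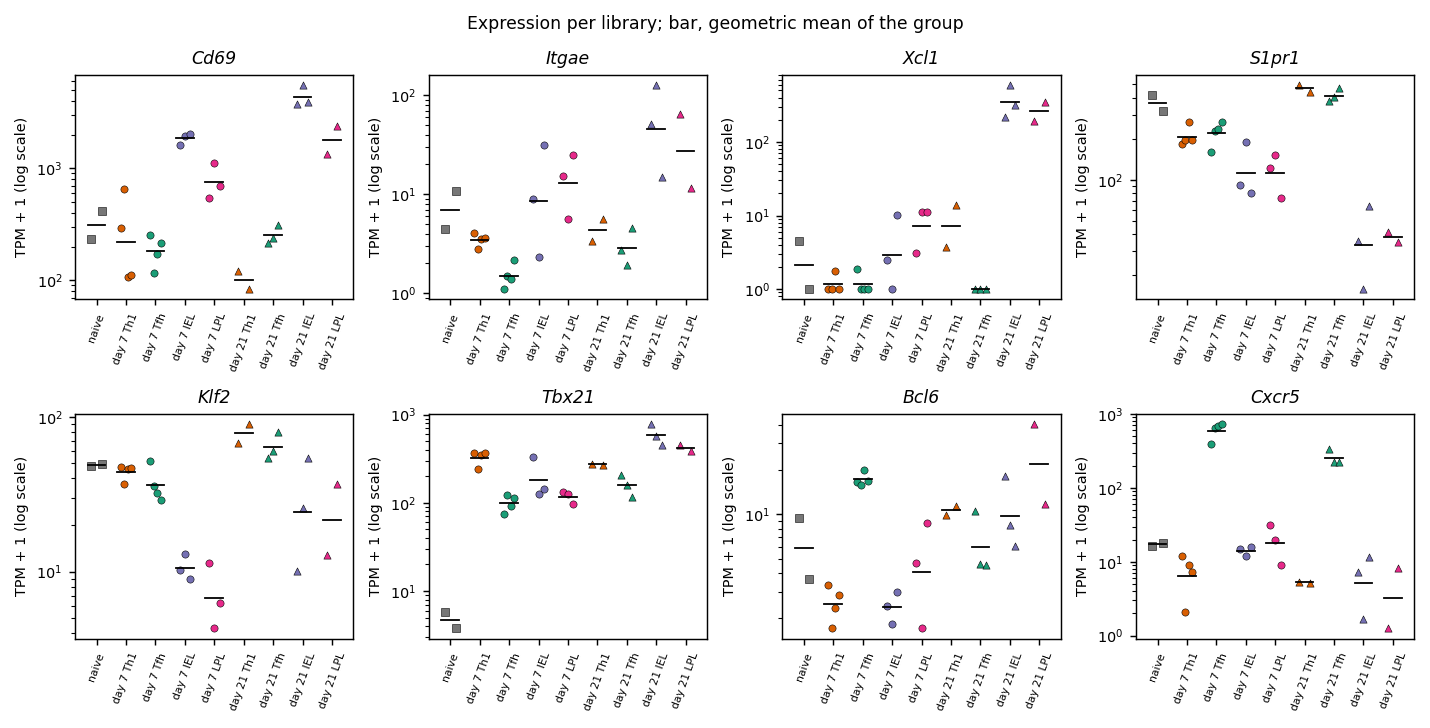
Expression of 8 genes in each library as TPM + 1 on a log axis, by group, with symbols as in the plot of principal components and a bar at the geometric mean of each group. Xcl1 lies higher and S1pr1 lower in every day 21 intestinal library than in any other library, and Cxcr5 lies at 224 TPM or above in every Tfh library.

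The comparison of day 7 splenic cells (Th1 and Tfh together) with naive cells asks how splenic cells differed before and after infection. At day 7 effector, inhibitory receptor and cell cycle genes were higher and genes of resting cells were lower by camera, though the cell cycle call was lost with an estimated correlation (adjusted p = 0.062). Plek, which encodes the cytoskeletal adaptor pleckstrin, rose from 0.264 ± 0.373 to 262 ± 233 TPM (SD, n = 2 and 8), Gzmk, a granzyme, had a log2 fold change of 6.49 ± 0.27, and Ly6c2, a surface marker of effector cells, of 6.26 ± 0.58. Igfbp4, an insulin-like growth factor binding protein, fell from 429 ± 36.1 to 0.108 ± 0.200 TPM, and Pdlim4 and Ifngr2, a chain of the interferon-gamma receptor, had log2 fold changes of -7.59 ± 0.41 and -6.43 ± 0.52. Tbx21 (5.26 ± 0.29) and the inhibitor of E proteins Id2 (2.59 ± 0.32) rose, and Tcf7 (-1.94 ± 0.25), which encodes the stem-like factor TCF1, and Id3 (-3.28 ± 0.52) were lower on average over the subsets. All of these passed the limma test with Benjamini-Hochberg adjustment, with Ly6c2 the weakest of the top 6 at an adjusted p of 1.3e-07. Of the subset means only that of Th1 cells lay below naive cells for the last pair: Tcf7 was at 1038 ± 22.4 TPM (SD, n = 2) in naive, 60.0 ± 13.8 TPM (SD, n = 4) in Th1 and 1287 ± 398 TPM (SD, n = 4) in Tfh cells. Id3 was at 553 ± 17.6 TPM (SD, n = 2), 3.46 ± 2.62 TPM (SD, n = 4) and 850.2 ± 143 TPM (SD, n = 4), and neither subset was tested alone against naive cells.

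Of the Th1 program, 19 of 26 measured genes rose and 2 fell (19 and 3 adjusted over the list alone), among them Ifng (6.18 ± 0.45), Nkg7 (6.14 ± 0.34) and the chemokine receptor Cxcr3 (6.04 ± 0.15). Camera gave an adjusted p of 1.7e-19, and an adjusted p of 7.6e-05 with an estimated correlation. Cytotoxicity genes rose in 15 of 22 cases (15 adjusted over the list alone), with Ccl5 at 5.44 ± 0.41 (camera adjusted p = 3.6e-16). Inhibitory receptors rose in 9 of 14 (9 adjusted over the list alone), led by Tigit (5.57 ± 0.27), Lag3 (5.45 ± 0.54) and Pdcd1 (3.38 ± 0.27), with a camera adjusted p of 1.3e-09. The memory and quiescence list fell in 15 of 20 genes (15 adjusted over the list alone), including the lymph node homing receptor Ccr7 (-6.00 ± 0.87), the survival cytokine receptor Il7r (-4.59 ± 0.54) and the repressor Bach2 (-3.79 ± 0.33). Its camera adjusted p was 3.9e-08. Cell cycle genes rose in 37 of 44 (38 adjusted over the list alone), such as Ccnb2 (6.18 ± 0.76) and Ube2c (5.13 ± 1.09), with a camera adjusted p of 5.7e-27 and an adjusted p of 0.062 with an estimated correlation. Glycolysis rose in 11 of 20 (12 adjusted over the list alone; camera adjusted p = 9.3e-08, and adjusted p = 0.062 with an estimated correlation), with the hexokinase gene Hk2 at 2.26 ± 0.42. Tfh program genes moved both ways, 10 up and 6 down of 28 (12 and 7 adjusted over the list alone), with the B cell helper cytokine Il21 (3.88 ± 0.64) and the factor Maf (3.58 ± 0.42) among those that rose. For this list the camera adjusted p was 0.0017, against an adjusted p of 0.26 with an estimated correlation.

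In all, 3626 of 10721 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1044 higher and 2582 lower. The median log2 fold change of all genes was -0.32, and with TMM factors the split was 1798 higher and 1332 lower; without naive replicate 5 the count fell to 1768.

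The day 7 Th1 and Tfh libraries compare the splenic subsets. Th1 program genes were higher and Tfh program genes lower in Th1 cells. Gzmb, which encodes granzyme B, was at 3190.1 ± 586 TPM in Th1 cells and 8.56 ± 9.33 in Tfh cells (SD, n = 4 each; log2 fold change 9.08 ± 0.74). The chemokine receptor Ccr2 (6.98 ± 0.36), the chemokine Ccl4 (6.78 ± 0.74), the inhibitory receptor Havcr2 (6.13 ± 0.36), Ifitm1 (5.86 ± 0.60) and Cx3cr1 (5.83 ± 0.53) followed, with adjusted p from 1.3e-12 for Ccr2 to 1.5e-06 for Ccl4 (limma, Benjamini-Hochberg). On the Tfh side stood Id3 (-7.76 ± 0.46), Ccr7 (-6.88 ± 0.78), Cxcr5 (-6.56 ± 0.59), Nsg2 (-6.42 ± 0.34), Sostdc1 (-5.86 ± 0.73) and Padi4 (-5.25 ± 0.62). The libraries of the subsets did not overlap for any of these 12 genes. Bcl6, the lineage-defining repressor of Tfh cells (chromosome 16, 23965052 to 23988852), was at 1.56 ± 0.693 TPM in Th1 and 16.2 ± 1.80 TPM in Tfh cells. Its antagonist Prdm1, which encodes Blimp-1, was at 19.4 ± 1.76 and 0.612 ± 0.251 TPM.

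Of the Th1 program, 23 of 26 genes were higher in Th1 cells (23 adjusted over the list alone; camera adjusted p = 2.2e-27). Of the Tfh program 25 of 28 were lower (25 adjusted over the list alone; camera adjusted p = 3.4e-24), including the folate receptor family gene Izumo1r (-4.66 ± 0.36) and Tox2 (-4.49 ± 0.44). Both calls held with an estimated correlation (adjusted p = 1.5e-05 and 0.0012). Cytotoxicity genes were higher in 17 of 22 (17 adjusted over the list alone), such as Ccl3 (5.69 ± 0.49) and Gzma (5.15 ± 0.86), with a camera adjusted p of 3.7e-15. Cell cycle genes were higher in Th1 cells in 42 of 44 (43 adjusted over the list alone), among them Ccna2 (3.85 ± 0.92) and Rrm2 (3.45 ± 0.71). The camera adjusted p was 3.1e-27, against an adjusted p of 0.079 with an estimated correlation. Memory and quiescence genes were lower in 14 of 20 (14 adjusted over the list alone; camera adjusted p = 1.5e-07), Tcf7 (-4.36 ± 0.22) included. Interferon-stimulated genes were lower in 10 of 31 (12 adjusted over the list alone), with Rsad2 at -1.92 ± 0.53 and Ifi44 at -1.82 ± 0.43 (camera adjusted p = 0.0013, and adjusted p = 0.50 with an estimated correlation).

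The limma test passed 2027 genes, 1074 higher and 953 lower in Th1 cells. Fits without each library in turn passed 1579 to 1933 genes.

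The comparison of day 7 small intestinal cells (IEL and LPL) with splenic Th1 cells asks how intestinal cells differed from splenic effector cells. A set of genes of tissue-resident T cells was higher and genes of recirculation were lower, while most Th1 and cell cycle genes did not pass the test. Osgin1, an oxidative stress response gene, was at 112 ± 26.9 TPM in the intestine and 0.964 ± 0.578 TPM in Th1 cells (SD, n = 6 and 4; log2 fold change 5.86 ± 0.34). The orphan nuclear receptors Nr4a2 (5.06 ± 0.58) and Nr4a1 (4.07 ± 0.60), the TGF-beta repressor Tgif1 (3.99 ± 0.35), Gpr34 (3.87 ± 0.38) and the gut-homing receptor Ccr9 (3.73 ± 0.32) were the next highest, with Nr4a1 the weakest at an adjusted p of 1.4e-04 (limma, Benjamini-Hochberg). The lowest were Mir1894 (-3.17 ± 0.85), Tmprss13 (-2.68 ± 0.43), G0s2 (-2.66 ± 0.45), Cmah (-2.59 ± 0.30), which modifies sialic acids, Fut7 (-2.51 ± 0.37), which makes selectin ligands, and Osbpl5 (-2.40 ± 0.34).

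Of the tissue residency list, 26 of 39 genes were higher and 0 lower (32 higher adjusted over the list alone), with Cd69 at 2.43 ± 0.39. Camera gave an adjusted p of 5.4e-39, and an adjusted p of 1.9e-04 with an estimated correlation. Itgae, the CD103 chain that binds E-cadherin (chromosome 11, 73090583 to 73147446), did not pass the test (1.62 ± 0.63, adjusted p = 0.12 by limma with Benjamini-Hochberg adjustment). Of the egress and circulation list, 20 of 32 were lower and 1 higher (23 and 1 adjusted over the list alone), including Klf2 (-2.38 ± 0.35; chromosome 8, 72319033 to 72321656), the factor that drives S1pr1, and S1pr5 (-2.28 ± 0.60), while Ccr7 was higher (2.82 ± 0.71). Its camera adjusted p was 1.6e-14. TGF-beta response genes were higher in 8 of 16 (10 adjusted over the list alone; camera adjusted p = 7.0e-09), among them Skil (3.39 ± 0.33) and Pmepa1 (2.47 ± 0.29). Cholesterol synthesis genes were higher in 7 of 22 (12 adjusted over the list alone; camera adjusted p = 2.0e-11), with the sterol sensor Insig1 at 2.06 ± 0.25. Treg program genes were higher in 5 of 10 (5 adjusted over the list alone; camera adjusted p = 2.6e-05), namely Tnfrsf4 (2.78 ± 0.27), Ctla4 (2.25 ± 0.24) and Il10 (2.19 ± 0.61) among others, which activated effector cells also express. Immediate-early and heat shock genes were higher in 11 of 36 (13 adjusted over the list alone; camera adjusted p = 7.2e-11, and adjusted p = 0.078 with an estimated correlation). Epithelial genes were also higher, with Fabp2 at 3.23 ± 0.45 and Fabp1 at 1.71 ± 0.42. The summed level of Fabp1, Fabp2, Reg3g and Apoa1 was 30.5 to 36.0 TPM in the day 7 IEL libraries.

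Of the Th1 program, 3 genes were higher, 6 lower and 17 did not pass, with Bhlhe40 (2.11 ± 0.36) higher and Tbx21 (-1.16 ± 0.23) lower. In all, 1013 genes passed (limma, Benjamini-Hochberg), 474 higher and 539 lower. With TPM rescaled without Rn45s the split was 430 and 848, with library weights 1946 genes passed, and without day 7 Th1 replicate 4 the count fell to 671.

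Against day 7 Tfh cells, the same intestinal cells differed both by effector state and by tissue. Gzmb was at 5818 ± 446 TPM in the intestine and 8.56 ± 9.33 TPM in Tfh cells (SD, n = 6 and 4), and Ccr9 had a log2 fold change of 7.53 ± 0.32 and Ccl4 of 7.22 ± 0.67. Id3 (-8.20 ± 0.42), Nsg2 (-5.69 ± 0.31) and Sostdc1 (-5.36 ± 0.67) were lowest. Itgae (2.83 ± 0.63, adjusted p = 0.0012) and Cd69 (2.69 ± 0.39, adjusted p = 1.8e-05) were higher by limma with Benjamini-Hochberg adjustment, and S1pr1 (-0.97 ± 0.29, adjusted p = 0.010), the receptor for the egress signal (chromosome 3, 115710433 to 115715072), was lower.

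Tissue residency genes were higher in 33 of 39 (34 adjusted over the list alone; camera adjusted p = 2.4e-21), Th1 program genes in 20 of 26 (21; 4.8e-18) and cytotoxicity genes in 19 of 22 (19; 3.1e-15), with the same values in parentheses, and these calls held with an estimated correlation. Tfh program genes were lower in 20 of 28 (22 adjusted over the list alone), with a camera adjusted p of 7.3e-14. Cell cycle genes were higher in 41 of 44 (42 adjusted over the list alone; camera adjusted p = 3.9e-22, and adjusted p = 0.073 with an estimated correlation). Cholesterol synthesis genes were higher in 19 of 22 (19 adjusted over the list alone), with Insig1 at 2.57 ± 0.25 and Cyp51 at 2.15 ± 0.25. For this list the camera adjusted p was 9.7e-10, against an adjusted p of 0.069 with an estimated correlation. The test passed 3717 genes (limma, Benjamini-Hochberg), 1696 higher and 2021 lower, or 1478 and 2872 with TPM rescaled without Rn45s.

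IEL and LPL of day 7 differed in 5 genes. The cell cycle gene Ccnd3 was at 234 ± 61.5 TPM in IEL and 106 ± 34.7 TPM in LPL (SD, n = 3 each; log2 fold change 1.15 ± 0.21), Tbc1d10c at 795 ± 34.4 and 461 ± 57.1 TPM, and the stress-response gene Chac1 at 1.93 ± 1.58 and 11.7 ± 2.50 TPM. Atp5s (1.57 ± 0.29) and Rbp2 (2.83 ± 0.49), a retinol-binding protein gene of enterocytes, complete the 5 genes that passed (limma, Benjamini-Hochberg adjusted p = 0.035 for each). The last pair fall below the abundance rule for named genes and were picked after their values were seen. Cd69 was at 1860.2 ± 219 and 782 ± 301 TPM, with an adjusted p of 0.49. No list had a member past the test over all genes. Epithelial markers (8 measured, 3 higher adjusted over the list alone) had a camera adjusted p of 2.9e-04, and an adjusted p of 0.23 with an estimated correlation, with Fabp2 at 2.69 ± 0.57 and Fabp1 at 1.51 ± 0.53. Cholesterol synthesis genes lay higher in IEL (median log2 fold change 0.35 above that of all genes; camera adjusted p = 3.0e-04, and adjusted p = 0.76 with an estimated correlation). Treg program genes lay lower (-0.57; camera adjusted p = 0.0048, and adjusted p = 0.23 with an estimated correlation). At an unadjusted p under 0.05, 779 genes differed. Of the 5 genes 1 passed with only these groups in the fit and none with the replicate block. The count was 14 with TMM factors (8 higher, 6 lower), 0 with genes of at least 10 TPM in at least 2 libraries, and between 0 and 46 when single libraries were left out.

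**Figure D3:**
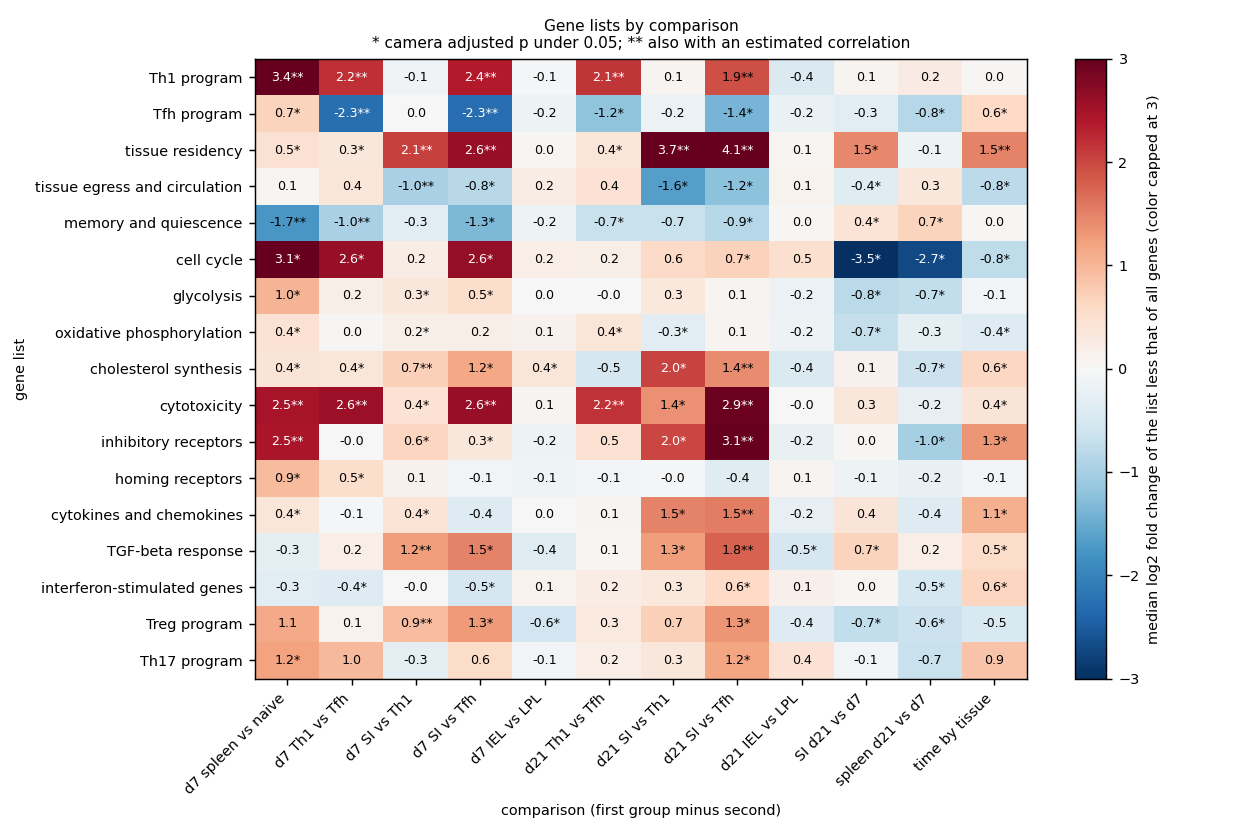
Median log2 fold change of each gene list less that of all genes, for the 12 comparisons, as colored cells with the value printed and the color capped at 3 in either direction. The residency list lies between 2.06 and 4.12 in the 4 comparisons of intestine with spleen, and the cell cycle list at -3.50 in the intestine and -2.71 in the spleen for day 21 against day 7. Stars in the cells mark camera adjusted p under 0.05, doubled where the call held with an estimated correlation.

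At day 21 the Th1 program was again higher in splenic Th1 than in Tfh libraries, and genes that share sequence with other genes differed too. The Tfh program was lower by camera, a call lost with an estimated correlation (adjusted p = 0.11). The 3 highest genes were Pisd-ps3, a pseudogene (382 ± 56.2 TPM in Th1, listed at 0 in every Tfh library), the retrogene Aldoart1 (7.06 ± 0.49) and Gstp2 (6.50 ± 0.46), a close paralog of Gstp1. All 3 belong to families of related sequence and are uncertain, because reads can be counted for a relative. The share of 50-base sequences found in another annotated gene was 54.3% for Gstp2 and 5.79% for Aldoart1, and none was computed for Pisd-ps3. Genes sharing at least 50% of their 50-base sequences with another annotated gene had a median log2 fold change of 1.17 (262 genes), and genes sharing none of -0.06 (5369 genes). The lowest were Cxcr5 (-5.61 ± 0.76), H2-Ob (-5.51 ± 0.56) and Ccr7 (-5.24 ± 1.01). Prdm1 (1.82 ± 0.31) and Id2 (1.82 ± 0.37) were higher and Id3 (-3.50 ± 0.60) and Tcf7 (-1.18 ± 0.29) lower in Th1 cells, with Tcf7 at an adjusted p of 0.0047 (limma, Benjamini-Hochberg). Cd3e was also higher in Th1 cells (1.63 ± 0.22), as was the T cell surface gene Thy1 (2.17 ± 0.28), and neither shares a 50-base sequence with another annotated gene.

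**Figure D4:**
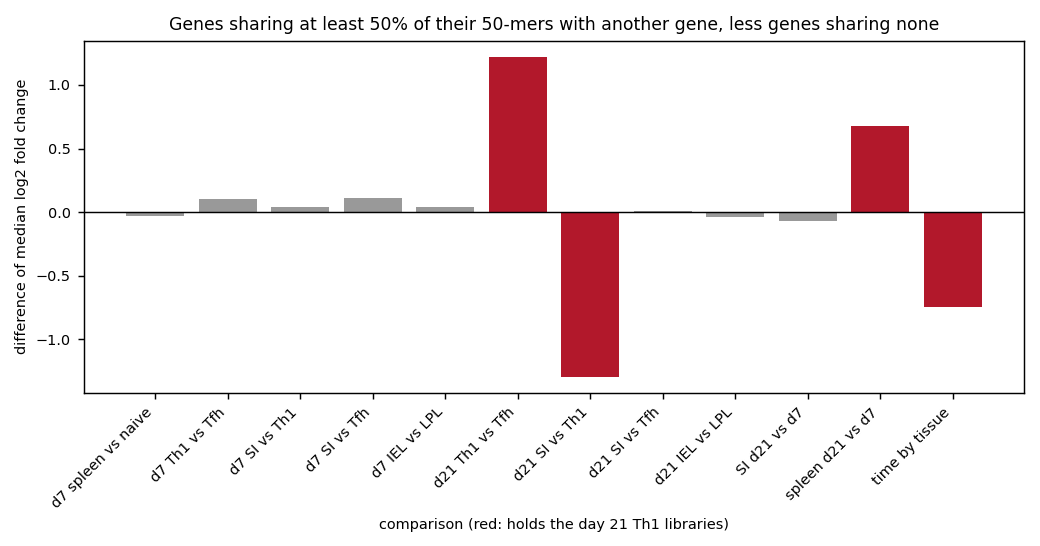
Median log2 fold change of the 262 genes sharing at least 50% of their 50-base sequences with another gene, less that of the 5369 genes sharing none, as a bar for each comparison. Red bars mark the comparisons that hold the day 21 Th1 libraries. The red bars reach 1.22 and -1.29, and the other bars lie between -0.07 and 0.11.

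Th1 program genes were higher in 19 of 26 (20 adjusted over the list alone; camera adjusted p = 8.1e-16, and 4.9e-04 with an estimated correlation), such as Gzmb (6.42 ± 0.96), Ccl5 (5.17 ± 0.48) and Ly6c1 (5.86 ± 0.56), which has close paralogs and is uncertain. Cytotoxicity genes were higher in 14 of 22 (16 adjusted over the list alone; camera adjusted p = 3.2e-09). Tfh program genes were lower in 16 of 28 (21 adjusted over the list alone), with the interleukin-6 receptor genes Il6ra (-4.42 ± 0.59) and Il6st (-3.74 ± 0.42). The camera adjusted p was 4.9e-08, against an adjusted p of 0.11 with an estimated correlation. Oxidative phosphorylation genes were higher in 12 of 33 (13 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.61 with an estimated correlation), led by Ndufa2 (2.07 ± 0.34) and Ndufa1 (2.05 ± 0.41), which share no 50-base sequence with another annotated gene. Bcl6 did not pass (0.81 ± 0.60, adjusted p = 0.37 by limma with Benjamini-Hochberg adjustment) at 9.63 ± 1.04 TPM in Th1 and 5.55 ± 3.41 TPM in Tfh cells (SD, n = 2 and 3).

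The test passed 2195 genes (limma, Benjamini-Hochberg), 1052 higher and 1143 lower in Th1 cells. Of the genes called higher at day 7, 319 were also called at day 21, against 105 for independent lists, and of those lower, 277 against 102. No library is shared by these comparisons. Both take each gene's spread from the same fit, so an overlap above that of independent lists can arise without shared differences. With TPM rescaled without Rn45s the split was 960 higher and 1591 lower and with limma-voom 1605 and 1160, library weights gave 3524 genes, and without day 21 Th1 replicate 2 the count fell to 1053.

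The comparison of day 21 small intestinal cells with day 21 splenic Th1 cells asks how the tissue and splenic populations differed 21 days after infection. Residency genes were higher in the intestine. Circulation genes were lower by camera, a call lost with an estimated correlation (adjusted p = 0.081). Nr4a2 was at 814 ± 418 TPM in the intestine and 2.23 ± 1.22 TPM in Th1 cells (SD, n = 5 and 2; log2 fold change 7.97 ± 0.75). Ramp3, a subunit of adrenomedullin and calcitonin-family receptors, was at 810.0 ± 1133 TPM against 0 in both Th1 libraries. Nr4a1 (7.57 ± 0.78), the cell cycle inhibitor gene Cdkn1a (6.60 ± 0.53), Tnfaip3 (6.51 ± 0.61), a brake on NF-kB, and Calca (6.28 ± 0.57), which encodes calcitonin and its gene-related peptide, completed the top 6. Ly6c1 (-7.63 ± 0.52) was among the 6 lowest genes. The other 5 were Pisd-ps3 (-8.57 ± 0.32), Rpl37rt (-7.07 ± 0.46), Csl (-6.42 ± 0.33), Gstp2 (-6.40 ± 0.43) and Aldoart1 (-6.27 ± 0.45), which belong to families of related sequence and are uncertain. Rpl37rt shared 38.5% and Csl 6.04% of their 50-base sequences with another gene, and Ly6c1, which has close paralogs and is uncertain as well, 32.8%. Cd69 (4.80 ± 0.51, adjusted p = 3.7e-07) and Itgae (3.02 ± 0.82, adjusted p = 0.0054) were higher, and S1pr1 (-3.73 ± 0.37, adjusted p = 5.1e-08) and Klf2 (-1.77 ± 0.45, adjusted p = 0.0030) lower, by limma with Benjamini-Hochberg adjustment.

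Tissue residency genes were higher in 36 of 39 (37 adjusted over the list alone), including the signalling regulator Rgs1 (6.18 ± 0.64) and the triglyceride enzyme gene Dgat1 (5.46 ± 0.70). Camera gave an adjusted p of 2.3e-25, and an adjusted p of 0.0023 with an estimated correlation. Egress and circulation genes were lower in 25 of 32 (26 adjusted over the list alone; camera adjusted p = 9.8e-09, and adjusted p = 0.081 with an estimated correlation), with Ly6c2 at -4.93 ± 0.62, Cmah at -4.07 ± 0.39 and S1pr5 at -3.95 ± 0.78. Inhibitory receptors were higher in 10 of 14 (10 adjusted over the list alone), such as Ctla4 (3.80 ± 0.31) and Cd160 (3.02 ± 0.39), with a camera adjusted p of 9.1e-06 and an adjusted p of 0.081 with an estimated correlation. Cytokines and chemokines were higher in 12 of 22 and lower in 5 (12 and 5 adjusted over the list alone), led by the dendritic cell attractant Xcl1 (5.38 ± 0.70; chromosome 1, 164931644 to 164935527), Tnfsf11 (4.94 ± 0.79) and Csf2 (4.07 ± 0.50). Camera gave an adjusted p of 0.013, and an adjusted p of 0.20 with an estimated correlation. Cholesterol synthesis genes were higher in 16 of 22 (16 adjusted over the list alone; camera adjusted p = 2.0e-10, and adjusted p = 0.079 with an estimated correlation), with Insig1 at 3.92 ± 0.32. TGF-beta response genes were higher in 9 of 16 (10 adjusted over the list alone; camera adjusted p = 9.2e-06, and adjusted p = 0.079 with an estimated correlation), led by the E-cadherin gene Cdh1 (4.50 ± 0.47). Immediate-early and heat shock genes were higher in 28 of 36 (28 adjusted over the list alone; camera adjusted p = 2.0e-10, and adjusted p = 0.081 with an estimated correlation), with Atf3 at 6.18 ± 0.71 and Dusp2 at 5.53 ± 0.87.

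Myeloid markers were higher in 14 of 21 and lower in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 8.1e-04, and adjusted p = 0.63 with an estimated correlation), and their level differed between libraries. The summed level of Lyz2, Apoe, C1qa, C1qb, C1qc, Csf1r and Adgre1 was 8851 TPM in day 21 IEL replicate 1, 622 TPM in replicate 4, 606 and 711 TPM in LPL replicates 3 and 4, and 3.21 TPM in IEL replicate 3, and at most 22.9 TPM in any other library of the study. With day 21 IEL replicate 3 as the only intestinal library, the list had a camera adjusted p of 0.44, while residency (2.6e-29), egress and circulation (6.0e-12) and inhibitory receptors (3.9e-05) kept their direction and passed. That library held the most epithelial RNA of the 5, with a summed level of Fabp1, Fabp2, Reg3g and Apoa1 of 106 TPM, and the epithelial list passed in that fit (camera adjusted p = 0.0022).

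**Figure D5:**
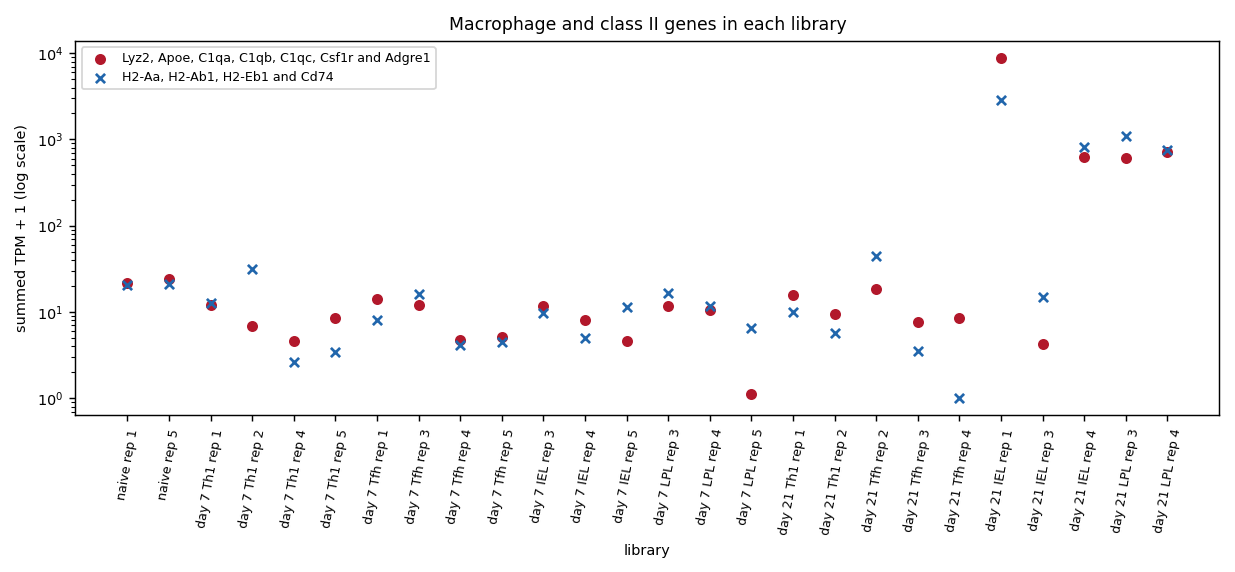
Summed TPM + 1, on a log axis, of 7 macrophage genes (circles) and 4 class II genes (crosses) in each of the 26 libraries. The macrophage sum lies between 606 and 8851 TPM in 4 of the 5 day 21 intestinal libraries and at or below 22.9 TPM in the rest.

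The test passed 4492 genes (limma, Benjamini-Hochberg), 1868 higher and 2624 lower, around an all-gene median log2 fold change of -0.15. Of the genes called higher against Th1 cells at day 7, 378 were also called at day 21, against 82.6 for independent lists, and of those lower 362 against 132. These lists too take each gene's spread from the same fit. With day 21 IEL replicate 3 alone 1892 genes passed, 1739 of them among those above, and without day 21 Th1 replicate 2 the count was 2854.

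Against day 21 Tfh cells, the intestinal cells again had higher residency genes. They had lower circulation genes by camera, but not with an estimated correlation (adjusted p = 0.11). Rgs1 was at 7488 ± 1704 TPM in the intestine and 20.4 ± 6.36 TPM in Tfh cells (SD, n = 5 and 3), and Gzmb at 2229 ± 338 and 6.95 ± 6.88 TPM. Cxcr5 (-5.97 ± 0.62), Il6ra (-5.55 ± 0.48) and Tdrp (-5.51 ± 0.42) were lowest. Xcl1 (8.22 ± 0.61), Cd69 (3.46 ± 0.44) and Itgae (3.63 ± 0.72) were higher and S1pr1 (-3.55 ± 0.33) and Klf2 (-1.47 ± 0.39) lower, with Klf2 the weakest at an adjusted p of 0.0054 (limma, Benjamini-Hochberg). Bcl6 was at 16.0 ± 13.9 TPM in the intestine and 5.55 ± 3.41 TPM in Tfh cells, with a log2 fold change of 1.27 ± 0.48 and an adjusted p of 0.042 by the same test.

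Residency genes were higher in 36 of 39 (37 adjusted over the list alone; camera adjusted p = 6.2e-42), cytotoxicity genes in 17 of 22 (17; 3.3e-19), Th1 program genes in 18 of 26 (20; 3.7e-14), inhibitory receptors in 11 of 14 (11; 2.5e-10), cholesterol synthesis genes in 17 of 22 (17; 7.1e-12) and immediate-early and heat shock genes in 21 of 36 (23; 4.3e-14). The values in parentheses are the count adjusted over the list alone and the camera adjusted p, and these 6 calls held with an estimated correlation. Among inhibitory receptors, Lilrb4a (5.36 ± 0.45), Entpd1 (4.93 ± 0.40), which degrades extracellular ATP, and Havcr2 (4.90 ± 0.38) were highest. Egress and circulation genes were lower in 20 of 32 (21 adjusted over the list alone; camera adjusted p = 6.2e-06, and adjusted p = 0.11 with an estimated correlation). Myeloid markers were higher in 15 of 21 (17 adjusted over the list alone; camera adjusted p = 1.4e-09, and adjusted p = 0.13 with an estimated correlation) and were high in the same 4 libraries. Lists of epithelial and innate lymphocyte markers also passed by camera with its preset correlation in this comparison. The innate lymphocyte call was lost with day 21 IEL replicate 3 as the only intestinal library. The test passed 3782 genes (limma, Benjamini-Hochberg), 1272 higher and 2510 lower, with an all-gene median log2 fold change of -0.25. With TMM factors the split was 1794 higher and 1722 lower, and with day 21 IEL replicate 3 alone 1226 genes passed.

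IEL and LPL of day 21 differed in more genes than at day 7, although that difference between days was not tested. Ramp3 was at 70.1 ± 40.5 TPM in IEL and 1919.9 ± 1013 TPM in LPL (SD, n = 3 and 2; log2 fold change -4.89 ± 1.17), Mest, an imprinted hydrolase-family gene, at 2.17 ± 1.88 and 83.7 ± 76.1 TPM. Car2, a carbonic anhydrase gene, was higher in IEL (3.53 ± 1.09, adjusted p = 0.044 by limma with Benjamini-Hochberg adjustment). The microRNA genes Mir7013 (4.89 ± 1.51) and Mir5121 (3.41 ± 0.95) were higher and Mir7078 (-5.99 ± 1.23) lower, which lie in few reads. Dgat1 (-2.78 ± 0.76), Fosl2 (-2.00 ± 0.54) and the cytokine genes Areg (-3.16 ± 0.69) and Tnfsf11 (-2.84 ± 0.86) were lower in IEL, and the epithelial gene Fabp2 (3.78 ± 0.64) was higher. Cd69, Itgae, S1pr1 and Klf2 did not pass. The TGF-beta response list had 1 lower gene of 16 (3 adjusted over the list alone), Epas1 (-2.42 ± 0.41), with a camera adjusted p of 0.040 and an adjusted p of 0.74 with an estimated correlation; no other list passed. The macrophage sum spanned 3.21 to 8851 TPM within IEL. The myeloid list passed without IEL replicate 1 (camera adjusted p = 7.4e-06), and in the other direction without IEL replicate 3 (camera adjusted p = 0.016). The test passed 1033 genes (limma, Benjamini-Hochberg), 693 higher and 340 lower in IEL around an all-gene median of 0.13, or 667 and 603 with TMM factors and 373 and 701 with limma-voom. The count was 365 with only these groups in the fit and 305 without day 21 LPL replicate 3.

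From day 7 to day 21 cell cycle genes fell in the intestinal cells, and residency and immediate-early genes rose, by camera with its preset correlation. With an estimated correlation none of these lists passed (camera adjusted p = 0.11, 0.19 and 0.36). Xcl1 rose from 5.47 ± 4.73 to 334 ± 161 TPM (SD, n = 6 and 5; log2 fold change 6.02 ± 0.51), Il7r from 12.3 ± 5.75 to 344 ± 90.2 TPM, and Atp8a2 (4.32 ± 0.50) and Atf3 (4.21 ± 0.52) also rose. The transferrin gene Trf (5.76 ± 0.44) and Il1b (5.38 ± 0.62), which myeloid cells express, were among the top 6 as well. Ube2c (-6.09 ± 0.84), Ccnb2 (-5.62 ± 0.59), Cdca8 (-5.46 ± 0.46), Nusap1 (-5.10 ± 0.65), Stmn1 (-5.02 ± 0.47) and Ccna2 (-4.98 ± 0.80), all genes of division, fell most, with Ccna2 the weakest at an adjusted p of 7.4e-05 (limma, Benjamini-Hochberg). Tbx21 (1.77 ± 0.22), Tcf7 (1.55 ± 0.19), Bcl6 (2.23 ± 0.40) and Klf2 (1.44 ± 0.33) rose, and S1pr1 (-1.65 ± 0.27) and Cxcr5 (-1.95 ± 0.51) fell.

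All 44 measured cell cycle genes fell (44 adjusted over the list alone; camera adjusted p = 3.5e-40, and adjusted p = 0.11 with an estimated correlation). Residency genes rose in 31 of 39 and fell in 2 (31 and 2 adjusted over the list alone; camera adjusted p = 1.7e-07, and adjusted p = 0.19 with an estimated correlation), with Qpct (3.87 ± 0.34) and Cdh1 (3.26 ± 0.35). Memory and quiescence genes rose in 11 of 20 (11 adjusted over the list alone), including the survival gene Bcl2 (1.96 ± 0.22) and Id3 (1.92 ± 0.40). For this list the camera adjusted p was 0.011, against an adjusted p of 0.38 with an estimated correlation and an adjusted p of 0.56 with day 21 IEL replicate 3 set against day 7 IEL. Glycolysis fell in 10 of 20 (10 adjusted over the list alone), such as Tpi1 (-1.83 ± 0.18), and oxidative phosphorylation in 15 of 33 (15 adjusted over the list alone). The camera adjusted p were 1.2e-05 and 3.8e-08, and the adjusted p with an estimated correlation 0.24 and 0.36. Immediate-early and heat shock genes rose in 25 of 36 (26 adjusted over the list alone), such as Fos (3.85 ± 0.94) and Jun (3.17 ± 0.62), with a camera adjusted p of 1.6e-05 and an adjusted p of 0.36 with an estimated correlation. Inhibitory receptors rose in 5 and fell in 3 of 14 (5 and 3 adjusted over the list alone), with Lag3 at -2.94 ± 0.42 and Cd101 at 2.37 ± 0.26. Treg program genes fell in 5 of 10 (5 adjusted over the list alone), including Il10 (-2.66 ± 0.58), with a camera adjusted p of 0.0034 and an adjusted p of 0.19 with an estimated correlation. Myeloid markers rose in 15 of 21 (15 adjusted over the list alone; camera adjusted p = 9.8e-04, and adjusted p = 0.52 with an estimated correlation), and 4 of the 5 day 21 libraries held the macrophage transcripts described above.

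The test passed 4702 genes (limma, Benjamini-Hochberg), 3342 higher and 1360 lower at day 21, around an all-gene median log2 fold change of 0.30. With TMM factors the split was 2172 higher and 2384 lower, and with day 21 IEL replicate 3 set against day 7 IEL 1694 genes passed, 1532 of them among those above.

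In the spleen, day 21 cells likewise had fewer transcripts of division and more of Il7r than day 7 cells, though the cell cycle list did not pass with an estimated correlation (camera adjusted p = 0.070). Il7r rose from 12.1 ± 11.2 to 603 ± 189 TPM (SD, n = 8 and 5; log2 fold change 5.90 ± 0.39). The heat shock genes Hspa1a (4.86 ± 0.88) and Hspa1b (4.29 ± 0.46), which shared 60.4% and 62.3% of their 50-base sequences with another gene and are uncertain, were next. Hspa1b was at 76.7 TPM or above in both day 21 Th1 libraries and at most 8.47 TPM in any other library. Ccnb2 (-5.45 ± 0.56), Lag3 (-5.05 ± 0.39), which restrains T cell activation, and Cdkn3 (-4.36 ± 0.45) fell most, all with an adjusted p of at most 4.6e-07 (limma, Benjamini-Hochberg). S1pr1 (1.05 ± 0.26), Klf2 (0.82 ± 0.31) and Id2 (1.30 ± 0.23) rose. Tcf7 (1.25 ± 0.18) and Id3 (1.33 ± 0.38) rose too, but between the Tfh groups alone their log2 fold changes were -0.34 and -0.80.

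Cell cycle genes fell in 41 of 44 (42 adjusted over the list alone; camera adjusted p = 1.1e-45, and adjusted p = 0.070 with an estimated correlation). Memory and quiescence genes rose in 14 of 20 (14 adjusted over the list alone; camera adjusted p = 0.0033, and adjusted p = 0.26 with an estimated correlation), Ccr7 (2.06 ± 0.64) and Bcl2 (1.90 ± 0.21) among them. Tfh program genes fell in 13 of 28 (13 adjusted over the list alone), with Il21 (-3.08 ± 0.47), Tox2 (-2.27 ± 0.36) and Pdcd1 (-1.87 ± 0.19). The camera adjusted p was 1.8e-07, against an adjusted p of 0.13 with an estimated correlation. Inhibitory receptors fell in 7 of 14 (7 adjusted over the list alone; camera adjusted p = 5.3e-06, and adjusted p = 0.13 with an estimated correlation), including Ctla4 (-2.30 ± 0.21). Interferon-stimulated genes fell in 8 and rose in 5 of 31 (8 and 5 adjusted over the list alone), with Rsad2 at -1.68 ± 0.43 and the antiviral gene Mx1 at -1.54 ± 0.47. For this list the camera adjusted p was 1.1e-04, against an adjusted p of 0.26 with an estimated correlation. The test passed 4634 genes (limma, Benjamini-Hochberg), 3905 higher and 729 lower, around an all-gene median of 0.38. With TMM factors the split was 1608 higher and 1910 lower, with TPM rescaled without Rn45s 2558 and 1172, and between the Tfh groups alone 2415 genes passed, 1895 of them among those above.

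Whether the change from day 7 to day 21 differed between intestine and spleen was tested as an interaction, where a positive value means that the intestinal change lay above the splenic change. Among residency genes that lay higher were Xcl1 (4.82 ± 0.70), Cdh1 (3.30 ± 0.47), Nr4a2 (2.97 ± 0.75) and Cd69 (1.57 ± 0.51). S1pr1 moved in opposite directions in the tissues (-1.65 ± 0.27 in the intestine and 1.05 ± 0.26 in the spleen), for an interaction of -2.70 ± 0.37 with an adjusted p of 4.2e-05 (limma, Benjamini-Hochberg). Bcl6 (1.94 ± 0.55, adjusted p = 0.018) and Tbx21 (1.56 ± 0.31, adjusted p = 0.0013) also passed by limma with Benjamini-Hochberg adjustment. The highest genes were Il1b (5.71 ± 0.85), Lgmn (5.51 ± 1.05), a lysosomal protease gene, and Trf (5.46 ± 0.60), which myeloid cells also express. The lowest were Snord52 (-5.01 ± 1.17), Ly6c1 (-4.52 ± 0.52) and Mir669n (-4.49 ± 1.04), all uncertain, as Snord52 shares all and Ly6c1 32.8% of its 50-base sequences with another gene and Mir669n is short.

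The residency list lay higher for 21 and lower for 1 of 39 genes (25 and 1 adjusted over the list alone; camera adjusted p = 2.5e-14, and 0.034 with an estimated correlation). Inhibitory receptors lay higher in 8 of 14 (10 adjusted over the list alone), with Cd160 (3.21 ± 0.39), Lag3 (2.11 ± 0.58) and Tigit (2.03 ± 0.28). The camera adjusted p was 3.3e-07, against an adjusted p of 0.12 with an estimated correlation. Egress and circulation genes lay lower in 11 of 32 (13 adjusted over the list alone), with Klrg1 at -2.57 ± 0.70 (camera adjusted p = 8.9e-04, and adjusted p = 0.32 with an estimated correlation). Cytokines and chemokines lay higher in 9 of 22 (11 adjusted over the list alone), including Csf2 (3.52 ± 0.50) and Il2 (2.91 ± 0.76). For this list the camera adjusted p was 7.0e-04, against an adjusted p of 0.17 with an estimated correlation. Cell cycle genes lay lower in 9 of 44 (9 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.62 with an estimated correlation), Stmn1 (-3.13 ± 0.65) first. Myeloid markers lay higher in 13 of 21 (15 adjusted over the list alone; camera adjusted p = 6.7e-08, and adjusted p = 0.30 with an estimated correlation) and were high in the 4 day 21 libraries named above. The interaction passed 1799 genes (limma, Benjamini-Hochberg), 653 higher and 1146 lower around an all-gene median of -0.11, or 964 and 998 with TMM factors. With only Tfh cells for the spleen 1025 genes passed, and with day 21 IEL replicate 3 set against day 7 IEL 340.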

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

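The splits of the libraries were planned; the tests of sequence sharing, gene length, day 7 subsets, cell type and handling were chosen only after the results were seen. In 34 tests of a measure within a group of 4 libraries, 2 had a library far from the others, and chance gives about 1 in 20. S1pr1 was at 264 TPM in day 7 Th1 replicate 4 and between 183 and 195 TPM in the others, and Tbx21 was at 238 TPM in day 7 Th1 replicate 2 and between 348 and 369 TPM in the others.

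The change from day 7 to day 21 differed between intestine and spleen for 1799 genes, and for these fixed genes the interaction on the log2 scale was 1.57 for Cd69, -2.70 for S1pr1, 1.94 for Bcl6 and 1.56 for Tbx21. Every LPL library lay above every Tfh library for Bcl6 at day 21, by a mean of 1.85 (n = 2 and 3). At day 7 every LPL library lay below, by a mean difference of -2.07. The difference of these differences was not tested. Bcl6 spanned 10.8 to 39.5 TPM in the day 21 LPL libraries, which also held macrophage transcripts (summed level 606 and 711 TPM). Likewise for Tbx21 LPL lay above Th1 at day 21 by 0.62 (n = 2 each) and below at day 7 (-1.47), which was not tested either. Both cases were picked for this reversal after the values of the fixed genes were seen. With so few libraries such separation can arise by chance.

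Genes that share sequence with other genes stood high in the day 21 Th1 libraries. The median log2 fold change of the 262 genes sharing at least 50% lay 1.22 above that of genes sharing none (bootstrap over genes 0.84 to 1.53), and in comparisons without these libraries the difference lay between -0.07 and 0.11. A bias by gene length is argued against by the smallest difference over 5 classes of length, 0.636, and a Th1 difference kept from day 7 by the value of 0.104 between the day 7 subsets (bootstrap over genes 0.02 to 0.19). The difference is consistent with reads counted differently among related genes in these libraries, and of the 102 genes at least 5 times above every other library in both day 21 Th1 libraries 43.0% of the 93 that have a share reach 50%, against 2.54% of all genes, and Cd3e, Thy1, Ndufa1 and Ndufa2 share none. For those, another technical difference or a biological one stays open and was not tested.

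Macrophage and class II genes were high in 4 of the 5 day 21 intestinal libraries. RNA of other cells would take the place of T cell RNA. Relative to all genes the CD4 T cell identity list differed by -0.112 between IEL replicates 1 and 3, the libraries with most and least macrophage RNA (bootstrap over genes -0.45 to 0.19). That range holds a loss of T cell RNA as well as none. The test therefore cannot tell whether the RNA came from another cell type. Expression by the T cells themselves stays open as well and was not tested. Lyz2 reached 2575 TPM in replicate 1, and how such RNA came into these libraries was not tested.

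Immediate-early and heat shock genes were higher in the day 21 intestine. In Tfh cells the list moved by 0.213 between the days relative to all genes, against 1.27 in the intestine. This argues against handling that moved every day 21 library as much as the intestinal ones. No interval was computed for the Tfh value and the Th1 libraries were left out, so a smaller effect of shared handling stays open. An effect of isolation from the intestine, alike at both days, cannot be told apart from a tissue effect, because the list differed by 1.07 more at day 21 but this difference did not pass 0.05 with fry. A stronger effect of isolation at day 21 alone stays open, as does a biological difference of resident cells, and neither was tested.

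Splits were run for the 8 comparisons with at least 3 libraries on each side, with the subsets of a side merged. They were drawn at random where over 100 were possible, in fits of only those libraries. In 6 of these comparisons all other splits that were run gave fewer genes. The other 4 comparisons have a side of 2 libraries and were not tested this way. Day 7 Th1 against Tfh gave 1928 genes and at most 6 in the other splits (1 of 35 splits as large), day 7 intestine against Th1 878 and 357 (1 of 100), day 7 intestine against Tfh 3198 and 96 (1 of 100) and day 21 intestine against Tfh 2157 and 4 (1 of 56). Day 21 against day 7 gave 3721 and 2336 in the intestine (1 of 100) and 3137 and 1070 in the spleen (1 of 100). A random division of the libraries thus rarely gave as many genes in these 6. The splits treat libraries as independent, which the labels do not state, so they cannot exclude chance if libraries of a group came from the same mice. For day 7 IEL against LPL the 10 splits are too few for a share under 0.05, with 3 genes in the real split and 5 in the highest other (2 of 10). For the interaction, fitted with subsets merged, 2 of 100 splits, the real one included, gave as many as the real 276 genes, the highest 741. The split with 741 genes keeps most spleen days and swaps most intestinal days, which turns an effect of time into an interaction. The splits therefore do not show what chance gives without an interaction. They cannot decide whether chance explains the 1799 genes of the reported fit, which kept the subsets apart.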

How the results depend on the processing

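Tests with only Tfh cells for the spleen, without the macrophage libraries, without Rn45s, with limma-voom, at 10 TPM or with less shared sequence were chosen after seeing the data. Over the alternatives of scaling and pseudocount no named gene or list reversed; with TMM factors 1039 of 1086 gene results kept their call, 37 lost it and 10 gained it. Counts within 1.5 times are not repeated. Day 7 IEL against LPL gave 14 genes with TMM factors (8 higher, 6 lower), 3 with only the groups compared (1 of the reported 5 among them), 1 with the replicate block (none of the 5) and 0 at 10 TPM, where fewer genes were tested; limma-voom gave 6 (2 higher, 4 lower), TPM without Rn45s 4 (all higher), and 779 genes had an unadjusted p under 0.05 in the reported limma fit. Day 21 IEL against LPL gave 365 with only the groups compared, against 1033 as reported. Day 21 Th1 against Tfh, with as many libraries, rose from 2195 to 2812 in such a fit. Fewer samples alone therefore do not account for the fall, and its cause was not tested. Library weights gave 1946 genes for day 7 intestine against Th1 and 3524 for day 21 Th1 against Tfh; the cause was not tested. Shares of higher and lower genes moved by over 10 percentage points with both cyclic loess and limma-voom in 6 comparisons, and some moves with other alternatives stand beside their comparisons. For day 7 spleen against naive they were 1044 and 2582 as reported, 1634 and 1406 with cyclic loess and 1497 and 1587 with limma-voom. For day 21 intestine against Tfh they were 1272 and 2510 as reported, 1944 and 1663 with cyclic loess and 1923 and 1637 with limma-voom. For day 21 IEL against LPL they were 693 and 340 as reported, 629 and 678 with cyclic loess and 373 and 701 with limma-voom. For the intestine with time they were 3342 and 1360 as reported, 2235 and 2062 with cyclic loess and 2269 and 2028 with limma-voom. For the spleen with time they were 3905 and 729 as reported, 1716 and 1698 with cyclic loess and 1910 and 1862 with limma-voom. For the interaction they were 653 and 1146 as reported, 1091 and 1005 with cyclic loess and 973 and 785 with limma-voom. With Tfh cells only, the spleen gave 2415 genes (1895 shared) and the interaction 1025 (724 shared). In the spleen Id3 (-0.80), Ndufa1 (-0.10), Ltb4r1 (0.081), Bcl6 (-1.51) and Tcf7 (-0.34) reversed, as Th1 cells were left out, and 2 genes passed in opposite directions. Without the 4 macrophage libraries, with fewer samples, 1892 genes passed for day 21 intestine against Th1 (1739 shared), 1226 against Tfh (1109 shared), 1694 with time in the intestine (1532 shared) and 340 for the interaction (280 shared). Reversed there were H2-Ab1 (-0.55), Lyz2 (-0.54), Fcer1g (-1.22) and the myeloid list (camera, adjusted p = 0.438) against Th1, and H2-Ab1 (-0.46) against Tfh. With time in the intestine Rsad2 (-0.13), Fabp2 (0.97), Apoe (-0.85), H2-Ab1 (-0.98), Fcer1g (-2.77) and the myeloid list (camera, adjusted p = 0.101) reversed, and 1 gene, Fcer1g, passed in both directions (limma, Benjamini-Hochberg adjusted p = 0.018). For the interaction H2-Ab1 (-0.65) and the myeloid list (camera, adjusted p = 0.566) did. Of 264 list tests 120 passed, 29 with an estimated correlation, 132 with fry, 128 with the replicate block and 111 of 252 without shared members. Homing receptors in the spleen with time reversed with fry (adjusted p = 0.0055), myeloid markers in day 21 Th1 against Tfh with camera and the block (adjusted p = 0.0499) and cytokines and chemokines in day 7 intestine against Tfh without shared members (camera, adjusted p = 0.0023); the cause was not tested. Leaving out 1 library gave 1768 (without naive replicate 5) to 3807 genes for day 7 spleen against naive and 1579 to 1933 for day 7 Th1 against Tfh. At day 7 it gave 671 (without day 7 Th1 replicate 4) to 1029 for intestine against Th1, 3169 to 3725 for intestine against Tfh, and 0 (without IEL replicate 3) to 46 (without IEL replicate 5) for IEL against LPL. At day 21 it gave 1053 (without day 21 Th1 replicate 2) to 1760 for day 21 Th1 against Tfh, 2854 (same library) to 4352 for intestine against Th1, 2941 to 3636 against Tfh, and 305 (without LPL replicate 3) to 904 for IEL against LPL. It gave 3664 to 4603 and 3422 to 4759 with time in intestine and spleen, and 1235 to 1868 for the interaction. No gene passed in opposite directions in these fits. The myeloid list in day 21 IEL against LPL ranged from a camera adjusted p = 7.4e-06 (without IEL replicate 1) to adjusted p = 0.66 (without LPL replicate 4), and reversed without IEL replicate 3 (adjusted p = 0.016). Where a group was left with 1 library, it was assumed to vary like the others. Of library pairs with the same replicate number 7 of 16 at day 7 and 2 of 8 at day 21 correlated above 0.1, against 16 of 57 and 2 of 29 with different numbers, so the rule that every such pair does was not met and no pairing was used; the block lost 66 and gained 14 of 1086 gene calls. Planned filters of at least 1 or 5 TPM and no filter removed no gene and test nothing, and planned edgeR and DESeq2 fits on recovered reads were not run, since the unit is TPM. Small changes were often missed with these numbers of libraries, and depth was not varied: 1.5-fold changes were recovered for 13.2% (day 21 IEL against LPL) to 58.4% (spleen with time) of simulated genes over 11 comparisons. The simulated genes shared a common dispersion, so these rates do not cover genes that vary more.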

Other observations

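The genes and sets in this part, other than the gene lists, were chosen after the values were seen. In 28 genes the lowest of the 5 day 21 intestinal libraries lay at least 5 times above the highest of the 15 spleen libraries, naive cells included. They included the E-cadherin gene Cdh1 at 30.7 ± 17.6 TPM (SD, n = 5), Xcl1 at 334 ± 161 TPM and the neuropeptide gene Calca at 132 ± 139 TPM. Others were the prostaglandin D synthase gene Hpgds at 29.9 ± 10.1 TPM and the glycogen phosphorylase gene Pygl at 34.1 ± 21.4 TPM. Gpr34 was at 153 ± 62.3 TPM, Fgl2 at 166 ± 40.9 TPM and the glycosyltransferase gene B3galt5 at 34.5 ± 19.9 TPM. Many of the 28 were immediate-early or stress-response genes, such as Atf3 at 84.2 ± 32.3 TPM, Junb at 12089 ± 3795 TPM and Nr4a1 at 2843 ± 1540 TPM. Nr4a2, Nr4a3, Fosl2, Crem and Gadd45b were among them too. For such genes an effect of isolation from the intestine stays open, as described above. In 12 genes the highest day 21 intestinal library lay at least 5 times below every day 21 spleen library, among them S1pr1, Cmah and the neuropeptide receptor gene Vipr1.

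Lists not described above were those of homing receptors, Th17 genes, conventional CD4 T cell identity and innate lymphocyte markers. Homing receptors moved both ways, with 10 of 22 higher and 4 lower in day 7 spleen against naive cells (10 and 4 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.059 with an estimated correlation). In day 21 intestine against Tfh, 8 were higher and 11 lower (camera adjusted p = 0.25), with Itga1 at 6.95 ± 0.28 and Ccr9 at 6.56 ± 0.36. Of 8 Th17 genes, 3 were higher and 2 lower in that comparison (camera adjusted p = 0.030, and adjusted p = 0.14 with an estimated correlation, and adjusted p = 0.081 with day 21 IEL replicate 3 as the only intestinal library). Of 17 identity genes, 9 rose and 1 fell in the intestine from day 7 to day 21 (camera adjusted p = 0.39), with Cd4 at 0.82 ± 0.20. All 5 innate lymphocyte markers rose there (camera adjusted p = 0.057), including Tyrobp (3.01 ± 0.65) and Fcer1g (2.28 ± 0.88), which myeloid cells also express, and Klre1 (2.61 ± 0.62). With day 21 IEL replicate 3 as the only day 21 intestinal library, Fcer1g passed in the opposite direction, with a log2 fold change of -2.77 (limma, Benjamini-Hochberg adjusted p = 0.018). In other comparisons the innate lymphocyte list did pass by camera, among them day 21 intestine against Tfh and the interaction. Both of these calls were lost with day 21 IEL replicate 3 as the only day 21 intestinal library, a fit that rests on that 1 library. Lists with fewer than 5 measured members were not tested: B cell (4 measured), CD8 T cell (3), erythroid and platelet (3), stromal and endothelial (3) and plasma cell (2) markers. No erythroid or platelet marker passed in any comparison, and the B cell marker Cd22 was at 13.1 ± 13.1 TPM (SD, n = 8) in day 7 spleen and listed at 0 in both naive libraries.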
